A study of Mus musculus with 23 samples.

How the data were processed

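The RNA values were deposited by the authors in the form of expected counts per gene, whole numbers in the file, for 35645 genes named by symbol in 15 libraries. Per the submitters' processing notes, Salmon 1.6 and DESeq2 were used with the mouse genome build mm10, and the notes give no further step between the reads and these counts. Library totals differed, and whether gene length entered the deposited values is not stated. The file gives no strand and no rule for reads shared between genes. Values of near-identical family members, such as the Ly49 receptor genes and the granzyme genes beside Gzmc, are therefore uncertain to the extent that reads were split among them. In 26 entries the symbol had been replaced by a date, which left the gene unnamed. These entries held 0.265% of all counts and stayed in the fits without a name.

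For ATAC-seq the deposited values were the authors' read counts per peak in 51412 peaks of 1 shared peak set, whole numbers for 8 libraries, with the gene and the type of each peak as the authors gave them. Bowtie2, SAMtools, MACS2 and the build mm10 come from the submitters' processing notes. Peaks spanned a median of 998 bases. A gene was assigned to all but 5520 peaks, and the distance from peak to gene was not part of the table.

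Both count tables were tested with the quasi-likelihood method of edgeR 4.0.16 in R 4.3.3. Features with low counts were removed with filterByExpr at a minimum count of 10, which left 17124 genes and 51292 peaks. Libraries were scaled with TMM factors, and dispersions and quasi-likelihood fits were robust. Each assay was fitted once over all of its libraries with 1 mean per group, which left 11 residual degrees of freedom for RNA and 4 for ATAC. All p-values for genes and peaks are 2-sided and Benjamini-Hochberg adjusted by this method within a comparison, and a call is an adjusted p below 0.05. Fold changes are log2 values from the fit with its standard error (SE). Levels are CPM (counts per library scaled to a common sum) on TMM-adjusted library sizes, given as mean ± SD over libraries. Fitted fold changes of genes near a count of 0 depend on the prior count. Where every library of a group held 0 counts, the text therefore gives only a lower bound against a floor of 3 counts over that group. Floors and intervals cover counting error only, because reads amplified without molecular identifiers are not independent molecules.

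The comparisons, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. For RNA, the rule named per comparison up to 12 genes with the highest and 12 with the lowest fold changes. They had to be called, reach 10 CPM in 1 of the groups, show no overlap between the groups' libraries and not be predicted genes. Members of the gene lists, Gzmc and S1pr5 could also be named. For ATAC, the rule took 5 peaks in each direction at 5 CPM or more, plus the peak with the smallest p for each of 24 genes. The gene lists were written from general knowledge of liver lymphocytes and of the cell types that a liver preparation can hold. Each of 26 lists, with the ribosomal protein genes and the mitochondrially encoded genes, was tested with camera of limma 3.58.1 at a preset correlation of 0.01, 2-sided, on log2 CPM with a prior count of 2. The p-values of camera were adjusted over the lists within a comparison. Camera with an estimated correlation and fry stood beside it, and the counts of members called are given over all genes and adjusted over the list alone.

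The RNA labels give each library's mouse, and 1 number is 1 animal, so the numbers pair the populations of a mouse. Deviations from the group means correlated between libraries of 1 mouse with a median r of 0.113 over 16 pairs, with a range from 0.0336 to 0.469. Over 68 pairs from different mice the median was -0.0266, with a range from -0.327 to 0.447. The highest of these was NK of mouse 1 with FMSP of mouse 3, both from mice 1 to 3. The consensus correlation within a mouse in limma voom was larger, at 0.497. The ATAC labels carry replicate numbers 1 and 2, and the correlations there ran from -0.120 to 0.179 over 12 pairs with a shared number. The fits reported had no term for the mouse. Fits with the mouse as a block are given where they change a call or move a count by more than 1.5 times. Mice 1 and 2 gave 1 library each, of NK and of DN. A fixed block fits each of these exactly, so neither informs the comparisons in the fits with it. In a principal component analysis of the RNA the leading component held 19.4% of the variance. It parted the 4 libraries of mice 1 to 3 from the 11 libraries of mice 4 to 6. Mice 1 to 3 hold at most 1 library of each population, too few for a comparison of their own, so values within mice 4 to 6 are given beside the pooled ones.

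The fits were tested on simulated data made from the spread and depth of these libraries, with 200 changed features. These were drawn only from features above a minimum mean CPM, so recovery of lower features that passed the filter was not measured. The simulated libraries were independent, without the shift between mice 1 to 3 and mice 4 to 6. The rates therefore hold for features of higher level in data without such a shift. For RNA with 4 against 3 libraries, 0.5% of genes changed 2-fold, 56.0% of genes changed 4-fold and 81.5% of genes changed 8-fold were called, with 0, 1 and 7 false calls. For ATAC with 2 against 2 libraries, 68.0% of peaks changed 2-fold were called with 11 false calls, and 100% of those changed 4-fold with 13 false calls. DESeq2 1.42.0, run on the same filtered features, served as the other tool. Alternatives fixed in advance were scaling by median of ratios or by library totals, no filter on low counts, a threshold of 0.01, fits of only the libraries compared, the mouse or replicate number as a fixed block, for RNA the mouse as a random effect in limma voom, and fits with 1 library left out. Chosen after the data had been seen were a term for mice 1 to 3, fits of mice 4 to 6 or without the 3 libraries high in hepatocyte transcripts for RNA, and cyclic loess for ATAC.

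Peaks called in the same direction in the liver and in the other organs were counted beside the number that independent lists would share, the product of both counts divided by the number of peaks tested. The gene assigned to each peak linked chromatin to RNA, with a 2-sided Fisher exact test across genes. The position of FMSP between DN and DP was measured in 1 mouse at a time, on genes called DP against DN without any library of that mouse.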

Results

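Natural killer (NK) cells circulate, while type 1 innate lymphoid cells (ILC1s) stay in tissues such as the liver and the salivary gland. Granzyme C, encoded by Gzmc, is a serine protease of cytotoxic granules, and a reporter mouse with a fate-map marker separates liver ILC1s by present and past expression of it. RNA was sequenced from 4 sorted liver populations of 6 mice. NK cells positive for an S1pr5-eGFP reporter gave 4 libraries. ILC1s that expressed granzyme C and carried the fate-map mark (DP) gave 4 libraries. ILC1s with the mark but no present granzyme C (FMSP, past expression) gave 4, and ILC1s with neither (DN, no history) gave 3. ATAC-seq, which measures accessible chromatin, covered NK cells of liver and spleen and ILC1s of liver and salivary gland with 2 libraries each, from 50000 sorted cells per library. For the ATAC libraries the sample labels disagree on the gate. Their cell type names the reporters, whereas the design text gives CD49b+ CD49a- for NK cells and CD49a+ for ILC1s.

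RNA libraries held 51641248 to 73309063 counts with a median of 62857384, and 14592 to 20057 genes had at least 1 count. ATAC libraries held 5609587 to 26944890 counts in peaks. Reads in promoter peaks made up 53.6% to 65.2% of them. Both sorting genes followed the labels. Gzmc stood at 2.31 ± 1.34 CPM in NK (SD, n = 4), 11.4 ± 1.87 in DN (n = 3), 30.4 ± 8.68 in FMSP (n = 4) and 374 ± 83.6 in DP (n = 4), with no overlap between any of the 4 populations. S1pr5, a receptor that guides lymphocytes out of tissue, stood at 510 ± 248 CPM in NK, 60.0 ± 34.9 in DN, 17.6 ± 3.45 in FMSP and 6.73 ± 3.48 in DP.

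**Figure D1:**
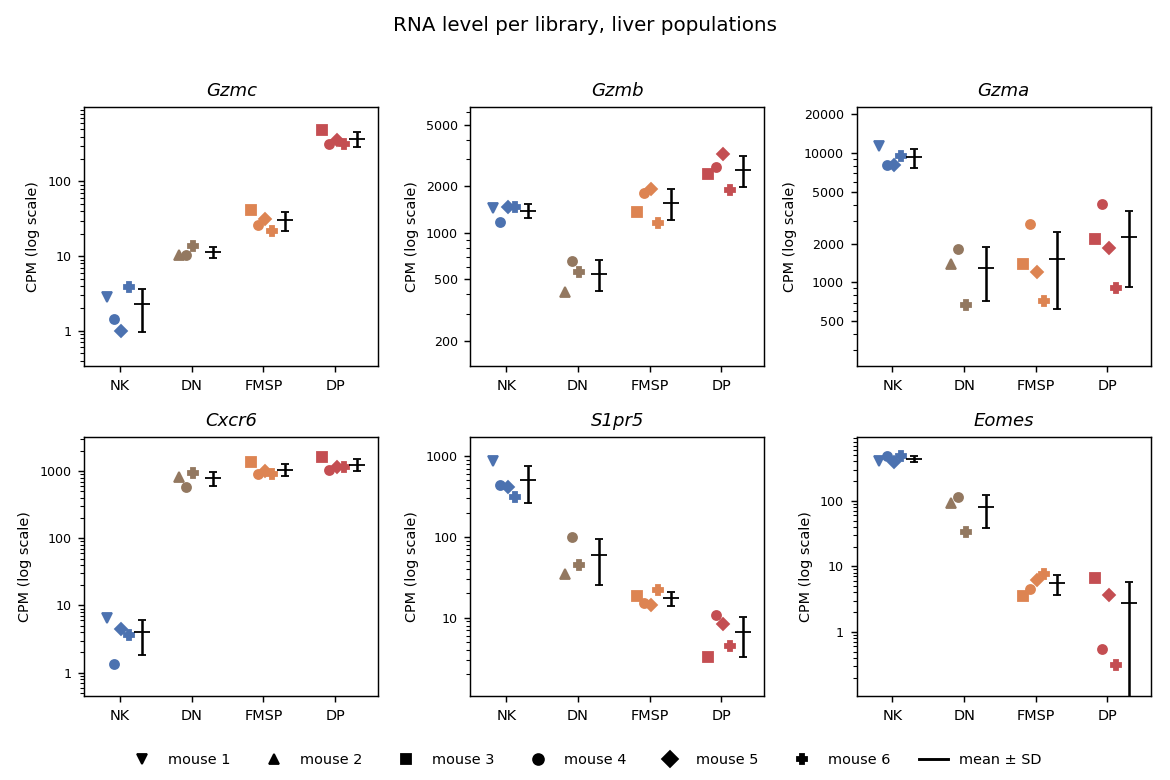
RNA level in CPM (log axis) of 6 genes in each liver library, with 1 point per mouse and black marks for the mean ± SD of NK (n = 4), DN (n = 3), FMSP (n = 4) and DP (n = 4). Gzmc rose stepwise from a mean of 2.31 in NK to 374 in DP, while Eomes fell from 440 to 2.79, with an SD of 2.98 in DP whose lower bar runs off the axis.

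The mean of the 3 ILC1 populations was compared with NK cells to find what liver ILC1s share. Cxcr6, a chemokine receptor that holds lymphocytes in the liver, averaged 1052 ± 282 CPM over the 11 ILC1 libraries and 3.98 ± 2.17 in the 4 NK libraries, a log2 fold change of 7.99 ± 0.46 (SE, adjusted p = 1.9e-07). Zfp683, the residency factor Hobit, was higher by 6.77 ± 0.49, the inhibitory receptor Cd200r1 by 7.03 ± 1.06 and the collagen-binding integrin Itga1 (CD49a) by 4.85 ± 1.02. Il7r, the interleukin 7 receptor, was higher by 4.59 ± 0.62, the death ligand Tnfsf10 by 4.36 ± 0.38 and Asb2 by 5.76 ± 0.36. Among the genes with the largest differences were also Atp8a2 at 9.69 ± 0.87 and Cd200r2 at 8.44 ± 0.77. Pdcd1, the checkpoint receptor PD-1, and the chemokine receptor Ccr8 had 0 counts in every NK library and were at least 1476-fold and 964-fold higher in ILC1s. Lrrn4 and Clec2l, also at 0 in NK, were at least 1463-fold and 1135-fold higher.

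Other genes were higher in NK cells. Eomes, the factor that sets NK identity apart, was lower in the ILC1 mean by -5.36 ± 0.54 (adjusted p = 1.7e-05). Cma1, the mast cell chymase gene, was at -7.32 ± 0.55, and the Ly49 genes Klra4 and Klra8 were at -6.29 ± 0.49 and -5.67 ± 0.51. Klf2, which drives S1pr1, was at -4.46 ± 0.32. Zeb2, Klrg1 and Itgam, genes of mature NK cells, were at -4.32 ± 0.66, -4.17 ± 0.43 and -4.50 ± 0.41. Tbx21, the T-bet gene that both lineages need, was at -1.01 ± 0.25 (adjusted p = 0.0259), with libraries that overlapped. It was at -0.58 without NK of mouse 1 (adjusted p = 0.180), and also not called without the 3 libraries high in hepatocyte markers (0.0995).

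In all, 1014 of 17124 genes were called in this comparison with edgeR, 496 higher and 518 lower in ILC1s. With the mouse as a block the count was 2168, and within mice 4 to 6 alone it was 2392. DESeq2 called 1850 genes and 2920 had an unadjusted p below 0.05. Scaling by library totals alone moved the median of all genes by 0.13 and the share of higher calls from 48.9% to 60.0%.

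The fixed lists described these differences as groups. All 16 conventional NK cell genes were lower in the ILC1 mean, over all genes and adjusted over the list alone (median -4.40, adjusted camera p = 1.5e-33), and the call held at adjusted p = 0.00149 with an estimated correlation. Of 20 liver ILC1 genes, 17 were higher and 1, the nucleotide sugar receptor P2ry14 at -3.42 ± 0.45, was lower, with the same counts adjusted over the list alone (median 4.48, adjusted p = 1.7e-27, and 0.00149 with an estimated correlation). Of 12 tissue egress genes 9 were lower and 0 higher by both counts (adjusted p = 4.5e-15, and 0.00521 with an estimated correlation). S1pr5, on whose reporter the NK cells were sorted, belongs to this list and to the conventional NK cell genes. It entered the tests of both lists in every comparison with NK. Tissue residency genes were less uniform. Of 18 members 6 were higher and 1 lower, and 7 and 2 were called adjusted over the list alone (adjusted p = 0.0247, and 0.244 with an estimated correlation). Cd69, a common residency marker, was not called against NK in any population, with 85.6 ± 25.6 CPM in DN, 90.8 ± 17.3 in DP and 96.0 ± 49.7 in NK.

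Cytokine and chemokine genes were higher in ILC1s in 9 of 16 members and lower in 1, by both counts (median 1.79, adjusted p = 4.3e-09, and 0.00972 with an estimated correlation). Il2, a T cell growth factor, rose by 8.66 ± 1.24, the inflammatory cytokine Tnf by 4.39 ± 0.76, the growth factors Csf1 and Csf2 by 3.52 ± 0.63 and 3.47 ± 0.50, and the chemokine Xcl1 by 2.22 ± 0.20. Ccl5 was the lower member, at -0.91 ± 0.22, and was not called without NK of mouse 1 (adjusted p = 0.103) or without the 3 libraries high in hepatocyte markers (0.0704). Ifng, the signature cytokine of both lineages, stood at 68.5 ± 18.1 CPM in NK and 110 ± 45.9 in DP. It was not called, but was higher with the mouse as a block (adjusted p = 0.00164) and within mice 4 to 6 (0.0158). Cytotoxic granule genes went both ways, with 2 of 14 higher and 6 lower, and 2 and 8 adjusted over the list alone (median -0.82, adjusted p = 0.0109, and 0.244 with an estimated correlation). Gzmc and Tnfsf10 were the higher members, while perforin (Prf1) was at -2.60 ± 0.23, granzyme A (Gzma) at -2.50 ± 0.34 and the granzyme B inhibitor Serpinb9 at -2.34 ± 0.21.

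Inhibitory receptors were higher in 4 of 13 members and lower in 1, Klrg1, and 6 and 1 were called adjusted over the list alone (median 0.94, also with Pdcd1 at its bound, adjusted p = 0.00128, and 0.0563 with an estimated correlation). Lag3 was higher by 4.07 ± 0.50 and Cd160 by 3.27 ± 0.23. Of 22 Ly49 and NKG2 family receptors 2 were higher and 7 lower, and 4 and 10 adjusted over the list alone (adjusted p = 2.1e-06, and 0.260 with an estimated correlation). Interferon-stimulated genes were higher in 8 of 24 members and lower in 0, and in 10 and 0 adjusted over the list alone (median 0.72, adjusted p = 1.2e-06, and 0.0563 with an estimated correlation). Rtp4 at 2.15 ± 0.23 and Oas3 at 2.81 ± 0.47, both interferon-induced antiviral genes, were among them. Stem-like and precursor genes moved in both directions, with 5 of 18 higher and 4 lower (7 and 5 adjusted over the list alone, adjusted p = 0.440). Tcf7, the TCF-1 gene, was alike in NK at 133 ± 28.2 CPM and in FMSP at 147 ± 63.7 CPM, whereas its relative Lef1 was lower in the ILC1 mean by -1.80 ± 0.26.

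Lymphocyte transcription factors were called in both directions, 6 of 31 higher and 9 lower, and 8 and 10 adjusted over the list alone. Their median was -0.07 and their mean 0.08, and the list did not pass the test (adjusted p = 0.446). Maf at 2.25 ± 0.37 and Ahr, the aryl hydrocarbon receptor, at 2.97 ± 0.44 were higher, and Irf8 was at -2.85 ± 0.27. Of 16 TGF-beta response genes 4 were higher and 1, Cd9 at -1.41 ± 0.12, was lower, and 5 and 2 were called adjusted over the list alone. That list had a median of -0.10, a mean of 0.51 and adjusted p = 0.740. Glycolysis genes (1 of 16 lower by both counts, Pfkp, adjusted p = 0.394) and the cell cycle genes (0 of 30 by both counts and 0 with DESeq2, adjusted p = 0.104) did not pass either. Within mice 4 to 6 the cell cycle genes passed as lower (2 of 30, median -0.67, adjusted p = 0.00135), where no estimated correlation was run. Over all libraries the list was lower than NK in DP and FMSP and higher in DN. With an estimated correlation none of these passed (adjusted p = 0.436, 0.295 and 0.488), and DN did not pass within mice 4 to 6 (0.439). For immediate early and heat shock genes 1 of 23 was higher, Jun, and 2 adjusted over the list alone, with a median of -0.03, a mean of 0.06 and adjusted p = 0.696. Cholesterol synthesis genes were higher in 1 of 21 members by both counts, Lss, with adjusted p = 0.0336 and 0.781 with an estimated correlation. That call was lost with the mouse as a block (adjusted p = 0.164), within mice 4 to 6 (0.295) and without DN of mouse 2 alone (0.186). Each of these settings takes DN of mouse 2 out of the comparison, so they are not separate checks.

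Markers of other cell types were measured in the same libraries. T cell markers were higher in ILC1s in 9 of 14 members and lower in 0, and in 10 and 1 adjusted over the list alone (median 2.47, adjusted p = 1.2e-10, and 0.0181 with an estimated correlation). Of the 14 members, 6 reached 10 CPM in NK cells and 9 in DP. The labels name no gate against CD3 for these sorts. Hepatocyte markers were higher in 1 of 18 members by both counts, Trf, at adjusted p = 0.0221 and 0.781 with an estimated correlation. The call was lost with the mouse as a block (adjusted p = 0.134), and within mice 4 to 6 it stood at 0.0959. The mean log2 CPM of that list was 5.96 in DN of mouse 2, 5.52 in FMSP of mouse 5 and 6.99 in FMSP of mouse 6, against 0.194 to 4.16 in the other 12 libraries. Lists of ILC3 (1 of 7 higher, Tmem176b, adjusted p = 0.0247, and 0.244 with an estimated correlation) and ILC2 markers (1 of 7 lower, Klrg1, adjusted p = 0.378) held few called genes, and the ILC3 call was lost with the mouse as a block (adjusted p = 0.0837) and within mice 4 to 6 (0.0932). The B cell list had 1 of 12 higher, Ighm (adjusted p = 0.378), and the neutrophil list 1 of 11, Mmp9 (adjusted p = 0.314). Kupffer cell, endothelial, stellate cell, red cell, ribosomal protein and mitochondrially encoded genes had 0 members called by edgeR each, with adjusted camera p from 0.144 to 0.740, where DESeq2 called 1, 2, 0, 0, 3 and 0.

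**Figure D2:**
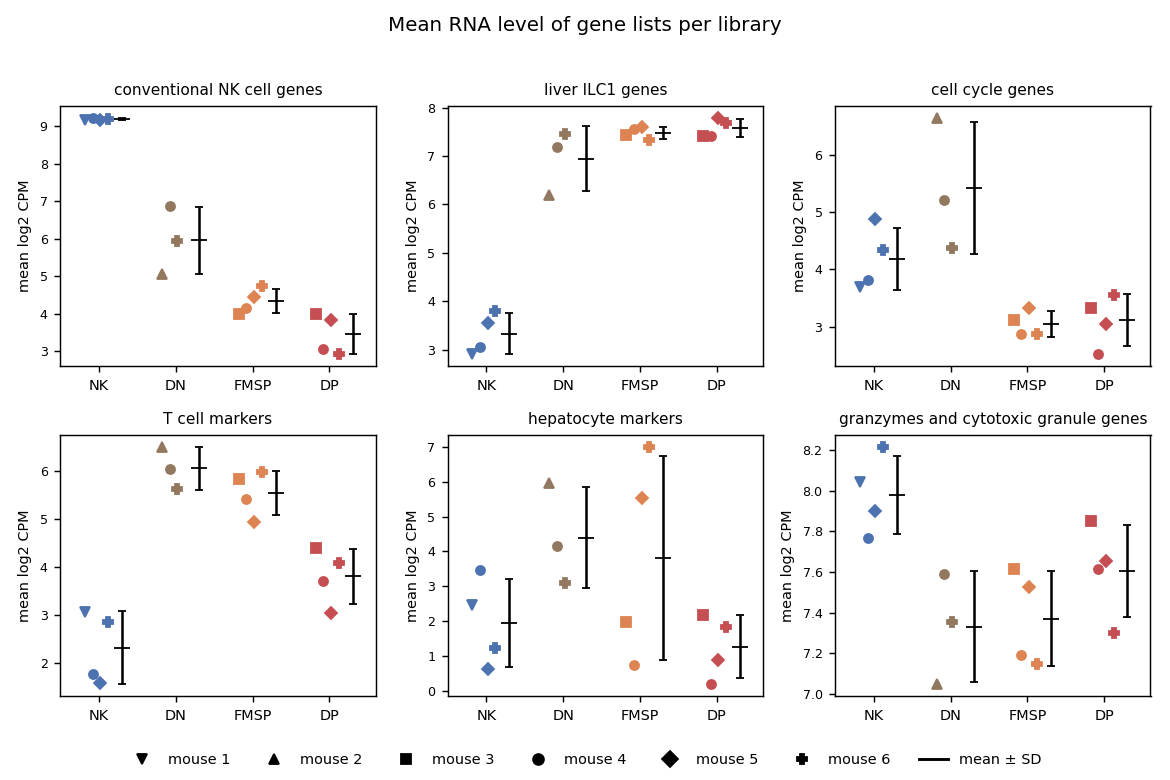
Mean log2 CPM of 6 gene lists in each liver library, with 1 point per mouse and black marks for the mean ± SD of NK (n = 4), DN (n = 3), FMSP (n = 4) and DP (n = 4). The conventional NK cell genes stood near 9.16 in NK, from 5.06 to 6.86 in DN and from 2.92 to 3.99 in DP, and the hepatocyte markers reached 6.99 in FMSP of mouse 6.

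Each ILC1 population was also compared with NK cells on its own. Gzmc was higher in DP by 7.34 ± 0.46 (adjusted p = 6.9e-07), in FMSP by 3.72 ± 0.39 (3.8e-05) and in DN by 2.31 ± 0.39 (0.00323), the last not called when only DN and NK libraries were fitted (0.147). Gzmb, the most abundant granzyme of DP, was higher than in NK by 0.88 ± 0.22 there (adjusted p = 0.0330), was lower in DN by -1.35 ± 0.24 (0.00540), and in FMSP differed by 0.17 ± 0.22 without a call (0.843). The call in DP was lost without any 1 library but DP of mouse 6 (adjusted p from 0.0570 to 0.132). Gzma was lower in all 3, at -2.06 ± 0.46 in DP, -2.60 ± 0.47 in FMSP and -2.84 ± 0.53 in DN, though within mice 4 to 6 it was not called in DP (adjusted p = 0.106) or DN (0.0609), nor in DP without DP of mouse 5 (0.0673), nor in FMSP without the 3 libraries high in hepatocyte markers (0.0833). Perforin was lower by nearly equal amounts, -2.56 in DP, -2.61 in FMSP and -2.65 in DN. Il7r was higher by 4.52, 4.55 and 4.70 in the same order.

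DP cells differed from NK cells in 699 genes, 429 higher and 270 lower. Pdcd1 was at least 1978-fold higher and Clec2l at least 1603-fold, whereas Cdh22, a cadherin gene, was at least 4690-fold lower and Klhl30 at least 3307-fold, the last not called with the mouse as a block (adjusted p = 0.0527). Conventional NK cell genes were lower in 15 of 16 members, and in 16 adjusted over the list alone (adjusted p = 8.0e-38, and 8.3e-04 with an estimated correlation). Inhibitory receptors (4 higher and 1 lower of 13, and 7 and 1 adjusted over the list alone) and interferon-stimulated genes (6 of 24 higher, and 10 adjusted over the list alone) passed the test also with an estimated correlation, at adjusted p = 0.0175 and 0.0256. With it neither list passed in FMSP (0.0501 and 0.0566), nor did the interferon-stimulated genes in DN (0.230). T cell markers were higher in DP as a list (adjusted p = 1.1e-04, and 0.143 with an estimated correlation). Cell cycle genes were lower in DP (1 of 30 by both counts, Stmn1, and 4 with DESeq2, median -0.87, adjusted p = 9.5e-05, and 0.436 with an estimated correlation). The call of Stmn1 was lost in 6 of 8 fits with 1 library left out (adjusted p from 0.0571 to 0.120). The block gave 1647 calls, mice 4 to 6 gave 1662 and DESeq2 gave 1499, and 2476 genes had an unadjusted p below 0.05.

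FMSP cells differed from NK cells in 697 genes, 424 higher and 273 lower. Cxcr6 was higher by 8.05 ± 0.47, Il2 by 9.04 ± 1.29 and Cd200r2 by 8.74 ± 0.80, while Cma1 was at -7.36 ± 0.82 and Klra8 at -6.65 ± 0.79. Liver ILC1 genes were higher in 16 of 20 members and lower in 1, and in 17 and 1 adjusted over the list alone (adjusted p = 4.2e-29, and 0.00116 with an estimated correlation). T cell markers were higher in 9 of 14, and in 11 adjusted over the list alone (adjusted p = 0.0131 with an estimated correlation). Cell cycle genes were lower in FMSP (1 of 30, Stmn1, 2 adjusted over the list alone and 4 with DESeq2, median -1.03, adjusted p = 4.0e-06, and 0.295 with an estimated correlation). Stmn1 was not called without FMSP of mouse 4 (adjusted p = 0.0592) or mouse 5 (0.0555), nor without the 3 libraries high in hepatocyte markers (0.0794). Hepatocyte markers were higher as a list (1 of 18, and 5 adjusted over the list alone, median 3.04, adjusted p = 6.6e-04). That call stood at adjusted p = 0.629 with an estimated correlation and at 0.855 without the 3 libraries high in them. The block gave 1682 calls, mice 4 to 6 gave 1620 and DESeq2 gave 1453, with 2409 genes at an unadjusted p below 0.05. Library totals moved the median of all genes by 0.11.

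DN cells differed from NK cells in 512 genes, 310 higher and 202 lower. Cd40lg, the helper T cell ligand of CD40, was at 0 in NK and at least 906-fold higher, the folate receptor gene Izumo1r at least 851-fold, and the T cell surface gene Cd5 was higher by 9.15 ± 2.00. Izumo1r was not called with the mouse as a block (adjusted p = 0.0565), within mice 4 to 6 (0.0762) or without any 1 library (0.0652 to 0.101). Cd40lg was not called without any 1 NK library or DN of mouse 6, nor without the 3 libraries high in hepatocyte markers (0.0510 to 0.0718). Cd5 was not called without NK of mouse 1, 4 or 5, nor without those 3 libraries (0.0547 to 0.0668). Cxcr6 was higher by 7.61 ± 0.47. T cell markers were higher in 7 of 14 members, and in 11 adjusted over the list alone (adjusted p = 0.0116 with an estimated correlation). Conventional NK cell genes were lower in 13 of 16, and in 16 adjusted over the list alone (median -3.10, adjusted p = 0.00515 with an estimated correlation). Cell cycle genes had 0 of 30 members called by edgeR, 5 higher with DESeq2 and 6 higher adjusted over the list alone, with a median of 1.29. Their list p of 3.6e-04 became 0.488 with an estimated correlation, 0.191 with the mouse as a block and 0.439 within mice 4 to 6. Hepatocyte markers were higher in DN as a list (1 of 18 by both counts, median 2.28, adjusted p = 2.3e-04). That p was 0.511 with an estimated correlation, 0.0659 with the mouse as a block, 0.0416 within mice 4 to 6 and 0.00416 without the 3 libraries.

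The DN comparison with NK gave 1191 calls with the block, 1458 within mice 4 to 6 and 1382 with DESeq2, and 2806 genes had an unadjusted p below 0.05. It gave 249 calls when only DN and NK libraries were fitted, and 341 without the libraries high in hepatocyte markers. Library totals moved the median of all genes by 0.20 and the share of higher calls from 60.5% to 75.5%.

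DP and DN cells, with present granzyme C and with no history of it, differed by both granzymes and by NK lineage genes. Gzmc was higher in DP by 5.03 ± 0.47 (adjusted p = 4.4e-04). Gzmb rose with it, from 541 ± 122 CPM in DN (n = 3) to 2542 ± 569 in DP (n = 4), a log2 fold change of 2.23 ± 0.25 (adjusted p = 0.00133). Gzma and perforin did not pass the test, at 0.78 ± 0.49 and 0.09 ± 0.32. Genes of NK cells were lower in DP. Eomes fell from 80.7 ± 42.1 CPM to 2.79 ± 2.98 (-4.85 ± 0.80, adjusted p = 0.0452), Cma1 from 40.9 ± 34.3 to 0.462 ± 0.329 (-6.46 ± 0.82, 0.00400) and S1pr5 from 60.0 to 6.73 (0.0223). The Ly49 genes Klra4 and Klra1 (-4.27 ± 0.68 and -3.12 ± 0.48) and Gramd3, from 43.9 ± 8.13 to 2.89 ± 0.163 CPM, were also lower. Rhpn1, chosen after its values were seen since it lies under 10 CPM, had 0 counts in DP and was at least 597-fold higher in DN, with 33.9 ± 13.4 CPM in NK.

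In all 10 genes were called, 2 higher and 8 lower in DP, and 1 of them is not analysed here. With the mouse as a block 22 were called, without Eomes (-5.50 ± 1.10, adjusted p = 0.123) and Klra4 (-4.76 ± 0.77, 0.0769), and within mice 4 to 6 all 10 were among 38. The mouse as a random effect in limma voom ended the calls of Klra1 (adjusted p = 0.0543) and Klra4 (0.067). DESeq2 called 510 genes, 138 higher and 372 lower, and 1754 had an unadjusted p below 0.05 with edgeR. With scaling by library totals 21 genes were called, the median of all genes moved by -0.12, and the fit of DP and DN libraries alone called 3. The count was 6 without DN of mouse 4 or without DP of mouse 5, 5 without DP of mouse 6 and 23 without DN of mouse 6. Leaving out 1 library ended the call of Eomes and of Klra4 in 5 of 7 fits each (adjusted p up to 0.180 and 0.196), that of Klra1 in 4 (up to 0.158) and that of S1pr5 in 3 (up to 0.113).

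As lists, conventional NK cell genes were lower in DP than in DN in 5 of 16 members and higher in 0, and in 12 and 1 adjusted over the list alone (median -2.55, adjusted p = 6.5e-16, and 0.0467 with an estimated correlation). Cell cycle genes had 0 of 30 members called by edgeR over all genes, 14 lower with DESeq2 and 19 lower adjusted over the list alone (median -2.61, adjusted p = 2.5e-18, and 0.0793 with an estimated correlation). The proliferation marker Mki67 stood at 48.0 ± 12.5 CPM in DN and 7.49 ± 4.17 in DP, and Top2a, which untangles replicated DNA, differed by -2.97 ± 0.58 without a call by edgeR (adjusted p = 0.0888). DESeq2 called both genes (0.0464 and 2.4e-05), and edgeR called Top2a without DN of mouse 6 (0.0397) and with a term for mice 1 to 3 (0.0487). Granule genes were higher in 2 of 14 members, and in 6 with 1 lower adjusted over the list alone (adjusted p = 2.8e-05, and 0.0793 with an estimated correlation). Gzmc, on which the cells were sorted, was 1 of the 2 and entered the list test. T cell markers had 0 of 14 called by edgeR, 7 lower with DESeq2 and 7 lower adjusted over the list alone (adjusted p = 3.0e-05, and 0.120 with an estimated correlation). Hepatocyte markers, with 0 of 18 called by edgeR by both counts and 3 lower with DESeq2, were lower as a list (median -3.22, adjusted p = 4.3e-07, and 0.275 with an estimated correlation). The mitochondrially encoded genes were also lower in DP, with 0 of 13 called by edgeR or DESeq2 and a median of -0.86. Their adjusted p was 0.00445, 0.544 with an estimated correlation, 7.6e-04 with the mouse as a block and 3.0e-05 within mice 4 to 6. Il7r and Tcf7 showed no call, at -0.18 ± 0.60 and -0.52 ± 0.31.

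Past expression (FMSP) was compared with no history (DN) and with present expression (DP). FMSP cells held 30.4 ± 8.68 CPM of Gzmc and 1560 ± 356 of Gzmb (n = 4), against 11.4 ± 1.87 and 541 ± 122 in DN (n = 3), log2 fold changes of 1.41 ± 0.39 and 1.53 ± 0.25 that edgeR did not call (adjusted p = 0.504 and 0.105). DESeq2 called both (0.0391 and 2.2e-08), and Gzmb was called with the mouse as a random effect (0.0111), without FMSP of mouse 6 (0.0468) and with a term for mice 1 to 3 (0.0365). Eomes stood at 5.49 ± 1.79 CPM and S1pr5 at 17.6 ± 3.45, also without a call by edgeR, but called by DESeq2 (2.6e-05 and 0.0158). Conventional NK cell genes had 0 of 16 members called by edgeR, 6 lower with DESeq2 and 8 lower adjusted over the list alone (median -1.43, adjusted p = 5.7e-11, and 0.0813 with an estimated correlation). Cell cycle genes had 0 of 30 called by edgeR, 12 lower with DESeq2 and 19 lower adjusted over the list alone (median -2.78, adjusted p = 3.8e-25, and 0.0749 with an estimated correlation). Mitochondrially encoded genes had 0 of 13 called by both tools and were lower as a list (median -0.56, adjusted p = 0.0144, and 0.828 with an estimated correlation). The single gene called by edgeR was Rhpn1, which fell outside the naming rule and was chosen after its values were seen. It had 8200 counts in NK, 1595 in DN and 1 in FMSP, a ratio of DN over FMSP of 1820 with a 95% counting interval from 326 to 71934 (adjusted p = 0.00331).

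That call was lost with the mouse as a block (adjusted p = 0.0703), without the libraries high in hepatocyte markers (0.0853) and when only FMSP and DN were fitted. DESeq2 called 233 genes and 1164 had an unadjusted p below 0.05. Within mice 4 to 6 edgeR called 3. The count was 2 without DN of mouse 2, 3 without DN of mouse 6 and 4 without FMSP of mouse 6.

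Between DP and FMSP the only gene called by edgeR was Gzmc, higher in DP by 3.62 ± 0.39 (adjusted p = 0.00246). Gzmb was higher by 0.70 ± 0.22 without a call. Hepatocyte markers were lower in DP as a list, 0 of 18 members with edgeR over all genes, 7 with DESeq2 and 14 adjusted over the list alone (median -4.08, adjusted p = 4.9e-12). That p was 0.226 with an estimated correlation, and 0.762 without FMSP of mice 5 and 6 and DN of mouse 2. Conventional NK cell genes had 0 of 16 called by edgeR, 2 lower with DESeq2 and 4 lower adjusted over the list alone (adjusted p = 2.8e-06, and 0.205 with an estimated correlation). T cell markers had 0 of 14 called by edgeR, 2 lower with DESeq2 and 5 lower adjusted over the list alone (adjusted p = 7.5e-09, and 0.151 with an estimated correlation). DESeq2 called 224 genes and 769 had an unadjusted p below 0.05. Without those 3 libraries, with 2 FMSP libraries left, Gzmc differed by 3.45 ± 0.55 and was not called (adjusted p = 0.506).

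How far FMSP lay from DN towards DP was measured in held-out mice, where 0 is the DN level and 1 the DP level. In mouse 6 the ratio was 0.459 over 6 genes chosen without that mouse, with a median version of 0.255. Rhpn1 had 0 counts in both FMSP and DP there, which fixes its ratio at 1, and without it the ratio was 0.289. Cma1 had 0 counts in DP, so that its distance depends on the prior count, and without both genes the ratio was 0.256. Gzmc, on which the cells were sorted, and Gzmb gave 0.274. Gramd3 and Sh2d1a, an adaptor of NK and T cell signalling, were lower in DP and gave 0.238. For mouse 4 the fit without its libraries called 0 genes with edgeR, so no value was obtained.

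Chromatin of liver ILC1s was compared with that of liver NK cells. Among peaks of 5 CPM or more, the largest gain in ILC1s lay at the promoter of Cxcr6 (chromosome 9, 123806040 to 123806853, mm10), with 26.0 ± 0.604 CPM in ILC1s and 3.16 ± 1.06 in NK (SD, n = 2), a log2 fold change of 3.01 ± 0.28 (adjusted p = 4.0e-24). The Gzmc promoter (chromosome 14, 56234259 to 56235420) was more accessible by 1.67 ± 0.27, a Zfp683 promoter (chromosome 4, 134052365 to 134053914) by 1.91 ± 0.23 and an Itga1 intron (chromosome 13, 115096737 to 115097501) by 1.91 ± 0.25. Less accessible were a Zeb2 promoter (chromosome 2, 45114497 to 45115188) at -2.77 ± 0.27 and the S1pr5 promoter (chromosome 9, 21246276 to 21246848) at -2.57 ± 0.34. Gzmc, S1pr5 and Itga1 (CD49a) each belong to a gate that the labels name, so these peaks are not independent of the sort. The Eomes promoter (chromosome 9, 118477403 to 118479687) was at -1.41 ± 0.21. All 3 peaks assigned to Klf2 were less accessible, and all 5 of Zfp683 and all 3 of Cxcr6 were more accessible. A peak beside Ifng (chromosome 10, 118455663 to 118456295) was at -2.61 ± 0.39, and of its 5 peaks 1 was higher and 2 were lower.

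Of 51292 peaks, 9583 were called, 5044 more and 4539 less accessible in ILC1s. Among promoter peaks 13.7% were higher and 4.86% lower, whereas among intergenic peaks 7.01% were higher and 11.1% lower. Whole libraries differed the same way, with 53.6% and 55.4% of reads in promoter peaks in liver NK and 57.2% and 60.4% in liver ILC1s. The count rested on single libraries. It was 5753 without liver NK replicate 1, 6212 without liver NK replicate 2 and 4298 without liver ILC1 replicate 2.

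Salivary gland ILC1s were compared with spleen NK cells, in libraries that share none with the liver comparison. The peak beside Klf2 (chromosome 8, 72329555 to 72330331) was at -4.13 ± 0.32 and the S1pr5 promoter at -3.81 ± 0.30. The Cxcr6 promoter was more accessible by 3.44 ± 0.27, the Gzmc promoter by 3.05 ± 0.27 and a Tmem176a exon (chromosome 6, 48846342 to 48847483) by 3.32 ± 0.30. A total of 24745 peaks were called, 11281 higher and 13464 lower. Cell type and organ differ together here, and the lowest and highest counts with 1 library left out were 19021 and 21173.

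Both comparisons called 2510 peaks higher in ILC1s, where independent lists of these lengths would share 1109, and 2877 lower, against 1192. Called in opposite directions were 310 peaks higher in the liver and 495 lower there. The shared total of 5387 became 3568 without liver NK replicate 2 and 2858 without liver ILC1 replicate 2. For the 24 genes fixed in advance, the liver's smallest-p peak had the same sign in both comparisons for 22, and 20 were called in the same direction in both. The other 2, the Il7r promoter (chromosome 15, 9528012 to 9528771) and the Tcf7 promoter (chromosome 11, 52273784 to 52275990), were called in opposite directions. Il7r was at 1.30 ± 0.24 in the liver and -1.60 ± 0.26 in salivary gland against spleen, and Tcf7 at 0.62 ± 0.19 and -1.38 ± 0.19. Of the 3 peaks assigned to Il7r, 1 was higher and 1 lower in the liver, and all 3 were lower in salivary gland against spleen. The liver call of Tcf7 was lost with only the libraries compared (adjusted p = 0.0532), without liver NK replicate 2 (0.0896) and without liver ILC1 replicate 2 (0.244).

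**Figure D3:**
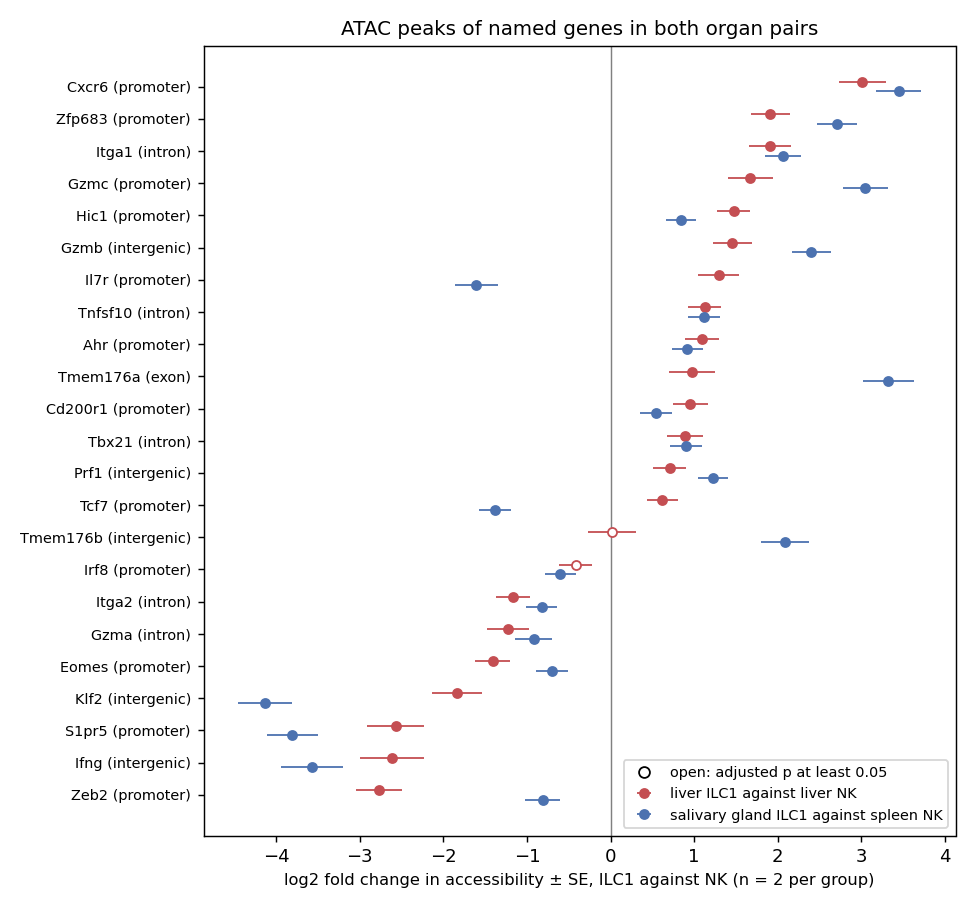
Log2 fold change in accessibility (ILC1 against NK, bars are ± SE, n = 2 libraries per group) of 1 peak for each of 23 of these genes, in red for the liver and in blue for salivary gland against spleen, with open points where the adjusted p is at least 0.05. Points of both colours share their sign for 21 genes, and those of Il7r (1.30 and -1.60) and Tcf7 (0.62 and -1.38) do not.

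A test of the difference between both comparisons called 15404 peaks, 6899 with a higher and 8505 with a lower value in salivary gland and spleen. A peak beside Tmem176b (chromosome 6, 48829243 to 48830325) was more accessible by 2.09 ± 0.28 there and by 0.02 ± 0.29 in the liver, a difference of 2.07 ± 0.40 (adjusted p = 7.5e-06). At the Gzmc promoter the ILC1 against NK difference was larger there by 1.37 ± 0.39 (adjusted p = 0.00305). For both peaks the NK cells of spleen and liver were also called as different. At the Gzmc promoter that difference was -0.90 ± 0.32 (adjusted p = 0.0163). It was not called with only the libraries compared (0.0502) or with cyclic loess (0.212). Between the ILC1s of both organs the Gzmc promoter was not called. It was called with scaling by median of ratios (0.0390), only the libraries compared (0.0342) and cyclic loess (0.00558). The Gzmc promoter stood at 23.2 CPM in salivary gland ILC1s and 16.5 in liver ILC1s, and at 2.81 in spleen NK and 5.19 in liver NK. The peak beside Tmem176b stood at 14.9 and 8.96 CPM in these ILC1s, and at 3.51 and 8.93 in these NK cells. The peak beside Klf2 closed more in salivary gland against spleen, by -2.30 ± 0.45 (8.7e-06). The Zeb2 promoter closed less, with -0.81 ± 0.21 there against -2.77 ± 0.27 in the liver (difference 1.95 ± 0.35, 8.3e-07), and of the 9 peaks assigned to Zeb2 5 were higher and 2 lower there, against 1 and 2 in the liver. Library totals moved the median of all peaks by 0.13.

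Organ was compared within each cell type. Salivary gland ILC1s had less accessible promoters of Il7r (-3.06 ± 0.26) and Tcf7 (-2.21 ± 0.19) than liver ILC1s, and more accessible promoters of Zeb2 (1.98 ± 0.27), Eomes (1.46 ± 0.20) and Itga1 (chromosome 13, 115101045 to 115102305, 1.28 ± 0.18). Of 24990 peaks called, 11688 were higher and 13302 lower. Library totals moved the median by -0.25 and gave 7403 higher and 17333 lower. Without salivary gland ILC1 replicate 2 the count was 17457.

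Spleen NK cells had a more accessible Klf2 promoter than liver NK cells (chromosome 8, 72318558 to 72320764, 1.10 ± 0.21), a call that cyclic loess ended (adjusted p = 0.130). A peak beside Gzmc (chromosome 14, 56229957 to 56231173) was less accessible at -1.86 ± 0.32, as was an Itga1 intron (chromosome 13, 115028075 to 115029104) at -2.59 ± 0.44. There were 20845 peaks called, 10707 higher and 10138 lower, with 43.8% of promoter peaks higher and 24.9% of intergenic peaks lower, in spleen libraries with 63.8% and 65.2% of reads in promoter peaks. The balance depended on the scaling. Library totals moved the median of all peaks by -0.38 and gave 5277 higher and 18704 lower, and cyclic loess moved it by 0.10 and called 7898 peaks, 3475 higher and 4423 lower. The count was 11046 without liver NK replicate 1 and 11383 without spleen NK replicate 1.

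Chromatin and RNA of the liver were set side by side, with genes as units that are not independent. Of genes with at least 1 more accessible peak in liver ILC1s and no less accessible one, 245 were higher and 39 lower in ILC1 RNA among those called. With the reverse chromatin, 15 were higher and 187 lower. The shares higher in RNA were 86.3% and 7.43%, an odds ratio of 77.2 with a 95% interval from 40.5 to 156 (Fisher exact test across genes, 2-sided, p = 1.2e-74).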

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

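Every test of an explanation in this part was chosen after the result it weighs had been seen. The biological difference that the design names, the history of granzyme C expression, stays open for all 3 patterns and was not tested.

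Conventional NK cell genes were higher in DN than in DP cells, with a median log2 fold change DP against DN of -2.55 over 16 genes. The libraries of mice 1 to 3 are not the source, since within mice 4 to 6 the median was -3.14 and the list passed the test. NK cells mixed into the DN sort would bring all of their strong genes in 1 proportion, and 37 such genes were used to estimate it. In mouse 2 only 32.4% of them lay within 2-fold of the median share of 3.39%, but that mouse has no NK or DP library, and the levels used came from other mice. An offset between mice could part the genes as well, so a mixture stays open there. In mice 4 and 6 the median shares were 15.5% and 7.10%, and 75.7% and 62.2% of the genes lay within 2-fold of them, so NK cells in the sort and a DN state nearer to NK cells cannot be told apart.

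Some T cell genes were higher in DN than in DP. The fold changes DP against DN of Cd3d, Cd3e, Cd5, Cd6 and Trac ran from -2.61 to -6.92, none of them called over all genes by edgeR and all called by DESeq2 (adjusted p from 9.0e-05 to 0.0318). Cd3d was also called with the mouse as a random effect in limma voom (adjusted p = 0.0487). The receptor chain genes Trbc1 and Trbc2 did not share this order, with 706 and 608 CPM in DN (n = 3) and 869 and 729 in DP (n = 4). T cells in the ILC1 sorts would move these 5 genes in 1 ratio. Over the 11 ILC1 libraries the SD around gene and library means was 0.686 of the SD between library means, too large for 1 ratio and too small to exclude it, so T cells and expression by ILC1s cannot be told apart for these genes. Cd3g did not fall with these genes, at 1.17 ± 0.68 DP against DN without a call (edgeR adjusted p = 0.604). That argues against T cells as the source of its higher level in ILC1s, 749 ± 367 CPM in DP (n = 4) against 7.51 ± 6.82 in NK (n = 4).

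Cell cycle genes were higher in DN than in DP and FMSP, with medians of -2.61 and -2.78 over 30 genes. The DN library of mouse 2 held the highest list mean, but the median DP against DN was -1.82 within mice 4 to 6, where the list passed the test, so that library alone is not the source. NK cells at the shares estimated above would bring 5.71% of the excess in mouse 4 and 10.1% in mouse 6, which argues against NK cells at those shares as the source in these mice. The summed level was 1616 CPM in DN, 808 in DP and 1106 in NK of mouse 4. In mouse 6 the excess was smaller, with 1135 CPM in DN, 917 in DP and 1227 in NK. DN of mouse 2, which has no NK or DP library of its own, could not be weighed in this way. Within mice 4 to 6 DN against NK did not pass the test (median 0.32, adjusted p = 0.439), while DP and FMSP were lower than NK (-1.10 and -1.32, adjusted p = 9.3e-06 and 6.1e-07). How far more division in DN or less in DP and FMSP makes up the difference is open. With an estimated correlation over all libraries the list did not pass for DP and FMSP against DN (adjusted p = 0.0793 and 0.0749) or against NK (0.436 and 0.295).

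Among single libraries, 7 of 96 groups of values held 1 library far from the other 3 by Dixon's criterion, where chance gives about 1 in 20, or 4.80. Interferon-stimulated genes had a mean log2 CPM of 4.11 in FMSP of mouse 3, against 4.60 to 4.68 in the other FMSP libraries. Glycolysis genes stood at 8.09 in FMSP of mouse 3, against 7.01 to 7.17, and at 7.93 in DP of mouse 3, against 6.77 to 6.96. Ribosomal protein genes stood at 4.18 in DP of mouse 3, against 3.46 to 3.50. ILC2 markers had a mean of 0.753 in NK of mouse 5, against 2.34 to 2.52. The total count of NK of mouse 6 was 70440987, against 62375891 to 63044029. In NK of mouse 1, 14592 genes were detected, against 17107 to 17202. The flagged libraries of mice 1 and 3 are each the only library of mice 1 to 3 in their group. The leading principal component parted mice 1 to 3 from mice 4 to 6, so for these flags that split and a single library or mouse cannot be told apart. For genes detected, FMSP and DP of mouse 3 were also the lowest of their groups, at 14713 and 15188. DN of mouse 2 was not, at 17283 against 16925 in DN of mouse 4 and 17869 in DN of mouse 6.

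The test of the difference between organs called 15404 of 51292 peaks. It set salivary gland ILC1s against spleen NK cells beside liver ILC1s against liver NK cells. Cell type and organ differ together in the first pair. The test therefore cannot tell a difference between salivary gland and spleen from a cell type difference that depends on the organ. At the Il7r promoter the value in salivary gland and spleen minus that in the liver was -2.90 ± 0.36 (adjusted p = 1.4e-13), and at the Tcf7 promoter it was -2.00 ± 0.27 (1.1e-11). Of 9 peaks assigned to Itga2, 2 were higher and 4 lower in the liver, and 1 was higher and 4 lower in salivary gland against spleen. A pair of Itga2 exon peaks were called in opposite directions. At chromosome 13, 114844965 to 114846653, the difference was -1.86 ± 0.26 (1.8e-10), and at 114848827 to 114849419 it was -3.46 ± 0.51 (9.6e-10).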

How the results depend on the processing

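Chosen after seeing the data were the term for mice 1 to 3, mice 4 to 6 alone, the fits without the 3 libraries high in hepatocyte transcripts, the gene list tests without DN of mouse 2, cyclic loess, the split of peaks by promoter and, for the position of FMSP, the block in choosing genes and the omission of genes at 0 in FMSP or DP. The other settings were planned. For each count below the cause of the change was not tested, except that a stricter threshold lowers counts by construction. Of 77 calls for the RNA genes named in the text, 54 held in every setting and none changed sign. Of 69 calls at peaks of the genes named in chromatin, 60 held. A promoter peak of Ifng, called at 0.63 in spleen against liver NK cells, changed sign with cyclic loess, to -0.0261. The replicate block ended the named calls of Eomes, Klra4 and Rhpn1 against DN and of Izumo1r and Klhl30 against NK, brought that of Ifng and changed no other named gene or peak. The ILC1 mean, DP, FMSP and DN against NK gave 1014, 699, 697 and 512 genes as reported. With adjusted p below 0.01 the counts were 587, 438, 391 and 260, with DESeq2 1850, 1499, 1453 and 1382, with the replicate block 2168, 1647, 1682 and 1191, with the mouse as a random effect in limma voom 1881, 1427, 1445 and 1114, with the term for mice 1 to 3 2175, 1461, 1499 and 1498, and with mice 4 to 6 only 2392, 1662, 1620 and 1458. DN against NK gave 249 with only the libraries compared and 341 without the 3 libraries high in hepatocyte transcripts. With 1 library left out the ranges were 728 to 1204, 537 to 619, 512 to 668 and 357 to 487.

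DP against DN gave 10 genes as reported, 5 with adjusted p below 0.01, 510 with DESeq2, 21 with library totals, 3 with only the libraries compared, 22 with the replicate block, 82 with the random effect, 84 with the term for mice 1 to 3, 38 with mice 4 to 6 only, and 5 to 23 with 1 library left out. In the fit of only DP and DN libraries Gzmb (adjusted p = 0.0981), Cma1 (0.284) and Eomes (0.354) were not called. Klra1 (0.195), Klra4 (0.237), S1pr5 (0.237) and Rhpn1 (0.237) were not called there either. FMSP against DN gave 1 gene, and with DESeq2 233, with only the libraries compared 0, with the random effect 11, with the term for mice 1 to 3 6, with mice 4 to 6 only 3, without the 3 libraries high in hepatocyte transcripts 0, and 1 to 4 with 1 library left out. For FMSP against DN the replicate block also gave 1 gene, which was not Rhpn1. DP against FMSP gave 1 gene, 224 with DESeq2, 0 without those 3 libraries and 1 to 1 with 1 library left out.

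For ATAC, liver ILC1 against NK gave 5700 peaks and the difference between organs 9774 with adjusted p below 0.01, and spleen against liver NK gave 7898 with cyclic loess. Leaving out 1 library leaves a lone sample that is assumed to vary like the other groups. It gave 4298 to 11425 peaks in the liver, 19021 to 21173 for salivary ILC1 against spleen NK, 17457 to 24494 between ILC1s, 11046 to 18072 between NK cells and 11206 to 15578 for the difference between organs. Shared ILC1 peaks numbered 3312 with adjusted p below 0.01 and 2858 to 5759 with 1 library left out. The replicate block moved the 9583 liver peaks to 9850, and no compared pair of ATAC groups had a correlation of same-numbered libraries below -0.1.

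Of 80 list calls in 196 tests, camera with an estimated correlation kept 22, fry 46, the replicate block 63, library totals 76, mice 4 to 6 only 64, the libraries without the 3 high in hepatocyte transcripts 56 and those without DN of mouse 2 61. The position of FMSP in mouse 6 was 0.459, and 0.274 for genes higher in DP, 0.510 for genes lower in DP, 0.289 and 0.296 for all and for lower genes with counts in FMSP or DP, 0.256 and 0.238 for those with counts in both, 0.255 for the median over genes and 0.487 with the replicate block in choosing the genes. The odds ratio between chromatin and RNA was 265 at adjusted p below 0.01, 130 with DP against NK, 120 for promoter peaks and 33.6 for other peaks. The planned limit to peaks within 20 kb of a gene was not run, since the table gives no distance. At the depth and spread of these libraries the simulated RNA fits called 0.5% of genes changed 2-fold and 81.5% of those changed 8-fold. The changed genes left out those of low mean level, and no shift between mice was simulated. Depth and spread were not varied apart, so which of them limits the calls is open.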

Other observations

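The counts of other splits of the samples were made after the gene counts were known. The levels of some genes in each population were as follows. Cd200r2, an activating member of the CD200 receptor family, stood at 82.4 ± 31.5 CPM in DN (n = 3), 208 ± 40.4 in FMSP and 279 ± 21.9 in DP (n = 4 each), against 0.491 ± 0.512 in NK. The death ligand Tnfsf10 stood at 109 ± 53.6 CPM in DN, 179 ± 43.6 in FMSP and 217 ± 59.2 in DP. Lef1 ran the other way, with 63.8 ± 32.3 CPM in DN, 23.6 ± 5.19 in FMSP and 15.7 ± 7.75 in DP. Trdc, the constant region of the T cell receptor delta chain that NK cells also transcribe, stood at 104 ± 28.0 in NK, 123 ± 23.6 in DN, 65.5 ± 31.6 in FMSP and 34.0 ± 3.30 in DP, and was lower in DP than in NK by -1.61 ± 0.31 (edgeR adjusted p = 0.00541). Between ILC1 populations edgeR called none of these 4. DESeq2 called Lef1 (adjusted p = 1.9e-05) and Trdc (5.6e-06) for DP against DN, and Lef1 for FMSP against DN (0.0207).

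In chromatin, Cmklr1, the chemerin receptor gene of NK cells, had a promoter peak (chromosome 5, 113626005 to 113627232) with 57.9 ± 7.83 CPM in spleen NK cells and 1.91 ± 0.382 in salivary gland ILC1s (n = 2 each), a log2 fold change of -4.88 ± 0.23. An intron of Klrb1 (chromosome 6, 128716918 to 128717937), of the NK1.1 receptor family, was at 4.62 ± 0.30. An exon of Lpin1 (chromosome 12, 16580185 to 16580972), a lipid phosphatase gene, was at -3.55 ± 0.26 in liver ILC1s against liver NK cells. Within NK cells, 4 promoter peaks of Tex14 on chromosome 11 were more accessible in spleen than in liver by 1.75 to 2.40, and an intergenic peak assigned to the keratin gene Krt8 (chromosome 15, 102006537 to 102007541) was at -3.53 ± 0.40.

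Other splits of the same libraries into groups of the same sizes were fitted to see how many genes they call. For the ILC1 mean against NK, 1 of 100 drawn splits, the real one, gave as many as 1014 genes, and the highest other gave 466. That other split set DN of mouse 2, FMSP and DP of mouse 3 and DP of mouse 5 apart, and so followed mice 1 to 3 in part, and within mice 4 to 6 the real comparison gave 2392. The real split also gave the most genes for DP against NK (1 of 35 splits, 699 against a highest other of 0), FMSP against NK (1 of 35, 697 against 1), DN against NK (1 of 35, 512 against 25) and DP against DN (1 of 35, 10 against 0). A mixed split puts real differences between populations into the spread within its groups, which lowers its count. The lowest shares possible were 1 of 100 and 1 of 35, so these counts alone do not exclude chance. For FMSP against DN 1 of 35 splits, the real one, gave 1 gene, against a highest other of 0. Other splits also gave 1 gene for FMSP against NK and DP against FMSP, so a count of 1 is too small to exclude chance, and the call was lost with the mouse as a block (adjusted p = 0.0703) and without the 3 libraries high in hepatocyte markers (0.0853). For DP against FMSP, 2 of 35 splits gave as many as 1 gene, the highest other being 1, so chance cannot be excluded from that count. The gene called, Gzmc, is the one the cells were sorted on, and its libraries did not overlap, with 320 to 496 CPM in DP and 21.8 to 42.0 in FMSP. Splits that part as many mice as the real one gave at most 19 genes for the ILC1 mean, 11 for DN against NK and 0 for the other 5.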
